A study of Drosophila melanogaster with 16 samples.

How the data were processed

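RNA from whole Drosophila embryos was measured on 16 single-colour expression arrays, 1 for each replicate of 4 groups: heat-shocked hsp-otd (4), heat-shocked hsp-Otx2 (4), untreated wild type (5) and heat-shocked wild type (3). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, heat-shocked embryos were collected over 12 h and aged for 4 h. They were then held at 37 °C for 25 min and left at 25 °C for 25 min. For untreated wild type the labels give stages 10 to 17 and no heat shock, collection or ageing time. Per the labels' protocols, RNA came from 200 mg of embryos, and 25 µg of it went into T7-primed cDNA and biotinylated cRNA.

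The deposited values are linear intensities, 1 per probe set and array, from -3962 to 34260, and 18.3% to 24.6% of those of an array are negative. How images were read, probes summarised or arrays scaled is not given in the sources used here. The deposited array means run from 460.2 to 1016.4, a ratio of 2.21, so no common scale is apparent. No pair of arrays was identical, and every column was used. Depth has no meaning for an array, and the number of arrays limits the precision.

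The platform's annotation is not given in the sources used here. The stem of each probe-set identifier (a CG number, a symbol or an older name) was looked up in a table of Drosophila gene names. This gave 1 symbol to 12943 of 14070 probe sets, several to 581 and none to 514, for 11211 genes. No coordinates were used. Identifiers that mark probes shared between transcripts (216) were kept. The 32 control probe sets were left out of tests and normalization.

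The values of the other 14038 probe sets were quantile normalized across the 16 arrays, raised to a floor of 20 and converted to log2. A share of 75.1% of deposited values lay above the floor. Probe sets above the floor in at least 3 arrays were tested (12301), and 1737 dim ones were not. A gene at the floor in every array of a group is given a fold of "at least" the ratio to the floor. Where only some arrays of a group lay above it, the mean and the fold change depend on the floor. Linear models with 1 coefficient per group were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 12 residual degrees of freedom and a median of 4.1 prior ones. A probe set passed at a Benjamini-Hochberg adjusted p below a threshold of 0.05, taken over all probe sets tested in that comparison. The comparisons were heat-shocked over untreated wild type, hsp-otd and hsp-Otx2 each over heat-shocked wild type, and hsp-otd over hsp-Otx2. Levels are geometric means of normalized intensity. "Changed" means that a probe set passed in the comparison described.

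The text names oc in every comparison and, per comparison, the 8 genes with the highest and the 8 with the lowest log2 fold change (5 and 5 between the lines). These had to pass, to be above the floor in every array of a compared group and to have a symbol other than a bare CG or CR number. The 2 highest and 2 lowest of any symbol were added. For each list described, up to 4 members with the smallest adjusted p are named. For changes shared by both lines, 6 genes per direction are named, by the smaller of their absolute fold changes. Where probe sets of a gene disagree, the text says so, and levels at the floor are those of the probe set named.

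Lists of genes, 27 in number, were written with gene names only: heat-inducible heat shock genes, constitutive chaperones and chaperonin, cytosolic ribosomal proteins, proteasome, replication-dependent and variant histones, sarcomere and muscle, neuronal and synaptic, neuroblast and neural progenitor, glia, head and brain patterning, segment polarity with Hedgehog and Wnt, Hox genes and cofactors, Notch signalling and Enhancer of split, cuticle and chitin, trachea, haemocyte and basement membrane, midgut and digestive enzymes, fat body and yolk, germ line and maternal, blastoderm segmentation and early zygotic, cell cycle and DNA replication, apoptosis, innate immunity, glutathione transferases and cytochromes P450, glycolysis, mitochondrial respiration, and cell adhesion. Each gene entered with the probe set of highest mean over all arrays, among 10032 genes with a tested probe set. Each list was tested against the other genes with camera (limma) at a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation, camera on ranked limma statistics, and fry were alternatives. For fry the values of each probe set were divided by limma's posterior standard deviation, a step added after the first run because fry's own scaling depended on an arbitrary basis.

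Changes shared by both lines were counted per direction and set beside the product of both counts over the probe sets tested, and beside 100 simulations of unchanged groups against the same control arrays. The floor, the linear model and the threshold were tested on simulated log2 values with 200 changed probe sets among 12301, far fewer than were called in the data. All groups had the same simulated spread. Normalization, the filter on dim probe sets, gene names, list tests and the overlap were not part of this test. For heat shock 22.4%, 32.8% and 62.1% of changes of 1.5-fold, 2-fold and 4-fold were recovered, and 2 unchanged probe sets were called. For hsp-otd the values were 17.9%, 38.8% and 59.1% with 5 called, and for hsp-Otx2 13.4%, 37.3% and 71.2% with 5 called. Between the lines 25.4%, 32.8% and 65.2% were recovered, with 10 called.

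Arrays of a group correlated at a mean r across probe sets of 0.904 in untreated wild type, 0.890 in heat-shocked wild type, 0.948 in hsp-otd and 0.942 in hsp-Otx2, and the median SD of log2 intensity was 0.406, 0.382, 0.206 and 0.229. Untreated replicates 4 and 5 had higher deposited means (950.6 and 999.1) than replicates 1 to 3 (598.7 to 662.2).

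Groups, comparisons, floor, normalization, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined. These alternatives were no normalization, median scaling, floors of 5 and 50, a generalized log without a floor, other filters, array weights, eBayes without a trend, only the compared groups in the fit, a replicate block, untreated wild type as the control, each array left out, the mean of a gene's probe sets, a stricter adjusted p and a fold of 1.5. Another 4 were added after the data were seen: array brightness (log2 of the deposited mean) as a covariate, untreated wild type reduced to replicates 1 to 3, 1 variance factor per group, and list tests with oc left out.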

Results

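Whole embryos of Drosophila melanogaster were profiled on 16 single-colour expression arrays. There were 4 groups: heat-shocked hsp-otd (n = 4), heat-shocked hsp-Otx2 (n = 4), untreated wild type (n = 5) and heat-shocked wild type (n = 3). The hsp-otd line 5A carries the fly gene otd, whose current symbol is oc, under a heat shock promoter. The hsp-Otx2 line carries its human relative in the same way, and the wild type is Oregon-R. Heat-shocked embryos were given 25 min at 37 °C and 25 min of recovery at 25 °C, and all embryos were at stages 10 to 17. Mean deposited intensity ran from 785.9 to 997.8 in the hsp-otd arrays, from 609.3 to 1016.4 in the hsp-Otx2 arrays, from 598.7 to 999.1 in untreated wild type and from 460.2 to 650.2 in heat-shocked wild type. The number of arrays limits the precision of every value given here. The p-values measure only the spread between arrays, since the labels do not say that replicates were separate collections. A group set to the floor in every array adds no spread, so SEs and p-values of such genes can be too small. Probe sets are named by the gene symbol that their identifiers lead to, and fold changes are log2 ratios of normalized intensity with their standard errors (SE).

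The otd transcript itself, oc (probe set OC_at), was 6322 in geometric mean normalized intensity in hsp-otd embryos and 71.2 in heat-shocked wild type, a log2 fold change of 6.47 (SE 0.54, adjusted p = 4.29e-07). The 4 hsp-otd arrays held deposited intensities of 6576, 8150, 8191 and 8367. In hsp-Otx2 embryos oc was 112, with normalized values from 96.6 to 127.3, and its difference from heat-shocked wild type did not pass, at 0.65 (SE 0.54, adjusted p = 0.373). Leaving out replicate 1 of heat-shocked wild type gave 1.52 with adjusted p = 0.0102 for that comparison. With untreated wild type as the control, oc was higher in hsp-Otx2, at 2.47 (adjusted p = 0.000466). In untreated wild type 1 of 5 arrays was above the floor of 20, and the geometric mean was 20.2. In heat-shocked over untreated wild type oc was higher by 1.81 (SE 0.52, adjusted p = 0.018), but the 3 heat-shocked wild-type arrays read 234.9, -16.5 and 76.7. That call was lost without replicate 1 of this group (0.96, adjusted p = 0.109) and without replicate 3 (1.76, adjusted p = 0.0554). It was also lost without normalization (1.25, adjusted p = 0.156), with a floor of 50 (0.95, adjusted p = 0.058), with array weights (1.52, adjusted p = 0.0758) and with only the compared groups in the fit (adjusted p = 0.132). Between the transgenic lines oc differed by 5.82 (SE 0.50, adjusted p = 1.67e-07). The arrays have no probe set for human Otx2, so the Otx2 transcript was not measured.

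**Figure D1:**
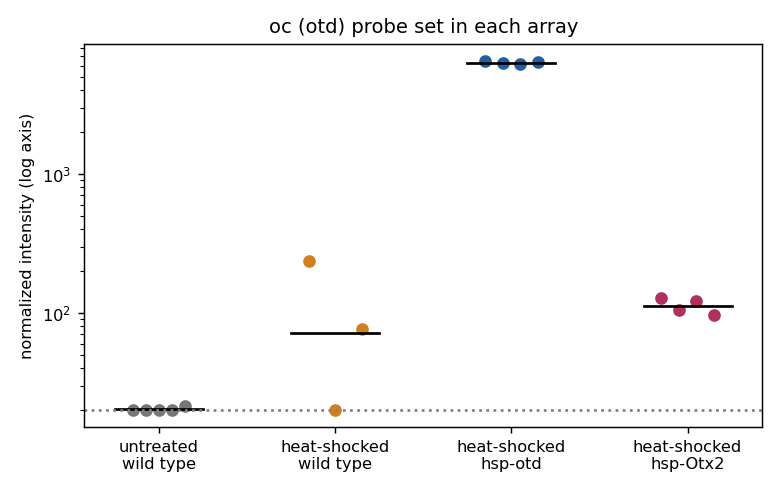
Normalized intensity of the oc probe set in each of the 16 arrays on a log axis, with the geometric mean of each group as a line and the floor of 20 dotted. The 4 hsp-otd arrays lie between 6213.3 and 6447.7, and no other array is above 234.9.

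Heat-shocked (n = 3) and untreated (n = 5) wild-type embryos were compared to ask what the heat pulse given to both transgenic lines does by itself. The labels give no collection or ageing time for the untreated embryos, so heat shock cannot be told apart from collection, age or batch. Heat shock protein genes rose: Hsp68 (HSP68_at) reached 16710 from below the floor in all 5 untreated arrays, at least 836-fold higher, with a log2 fold change of 9.71 (SE 0.06, adjusted p = 3.13e-23). Hsp26, above the floor in 2 of 5 untreated arrays and set to it in the others, rose to 14380, or by 8.25 (SE 0.66, adjusted p = 1.34e-07). Hsp22 rose from 319 to 19390, or 5.93 (SE 0.22, adjusted p = 6.88e-12). Cuticle transcripts fell: TwdlW, a Tweedle cuticle protein gene, dropped from 3749 to below the floor in all 3 heat-shocked arrays, at least 187-fold lower (-7.55, SE 0.17, adjusted p = 9.28e-15). Of the 12301 probe sets tested, 2770 (22.5%) passed, 1269 higher and 1501 lower, from 2443 named genes. At least 2-fold changes were found in 616 probe sets higher and 767 lower.

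Among the other genes with the highest fold changes were 6.66 for Hsp70Bbb, 6.53 for M7BP, 5.23 for Hsp23, 5.13 for AdamTS-A and 5.08 for Jon99Ciii (SE 0.20 to 0.58, largest adjusted p = 3.26e-07). The named probe sets of M7BP, AdamTS-A and Jon99Ciii were at the floor in untreated wild type, and that of Hsp70Bbb in 2 of 5 arrays, so for the former these are lower bounds of 92.7-fold, 34.9-fold and 33.8-fold. The other probe sets of M7BP lay above the floor there, at log2 levels of 8.65 and 4.88, and gave 1.35 with adjusted p = 0.00663 and 1.03 with adjusted p = 0.257. The genes with the lowest fold changes, after TwdlW, had values of -7.06 for Muc91C, -6.97 for Vajk1, -6.74 for Ccp84Ac, -6.23 for Ccp84Ag, -6.22 for Cpr66D, -6.09 for TwdlV and -5.95 for Cpr62Bb (SE 0.16 to 0.66, largest adjusted p = 9.42e-07). Muc91C, Vajk1, Ccp84Ac, TwdlV and Cpr62Bb were at the floor after heat shock, at least 133-fold, 125-fold, 107-fold, 68.3-fold and 61.9-fold lower. Ccp84Ag and Cpr66D were above it in 2 of 3 and 1 of 3 heat-shocked arrays, so their values depend on the floor. Other probe sets of Ccp84Ag gave -2.72 and -0.92, and that of Cpr66D gave -1.57.

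All 13 measured members of the list of heat-inducible heat shock genes rose (13 adjusted over the list alone), with a median of 3.73 (camera adjusted p = 6.49e-26). Hsp27 and Hsp67Bc changed by 4.65 and 2.87 (SE 0.15 and 0.08). Constitutive chaperones and chaperonin followed with 14 higher and 0 lower of 18 (16 and 0 adjusted over the list alone), a median of 0.67 and adjusted p = 3.81e-13, though only 2 passed without normalization. Members were 1.95 for Hsp110, 1.24 for Cdc37, 1.41 for Hsc70-3 and 0.67 for CCT8 (SE 0.06 to 0.11, largest adjusted p = 4.93e-07), and Cdc37 and CCT8 were not called without normalization (0.71 and 0.16). In cuticle and chitin genes the counts were 3 higher and 48 lower of 117 (5 and 49 adjusted over the list alone), with a median of -0.51 and adjusted p = 1.74e-11. Cpr65Ea fell from 12980 to 384 (-5.08, SE 0.09, adjusted p = 1.74e-16), and TwdlD changed by -3.18 (SE 0.08).

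Notch signalling and Enhancer of split genes, which act where neighbouring cells choose different fates, fell, with 0 higher and 12 lower of 18 (0 and 12 adjusted over the list alone), a median of -1.11 and adjusted p = 3.1e-09. Values were -2.20 for Ocho, -1.60 for Brd, -1.46 for E(spl)mgamma-HLH and -5.21 for E(spl)m5-HLH (SE 0.09 to 0.39, largest adjusted p = 6.6e-08), and E(spl)m5-HLH was at the floor after heat shock, at least 37.1-fold lower. Cell cycle and DNA replication genes had 1 higher and 10 lower of 25 (1 and 11 adjusted over the list alone), a median of -0.36 and adjusted p = 0.00129. Members gave -1.24 for PCNA, -1.28 for Cdk2, -2.64 for Mcm2 and -1.06 for Incenp (SE 0.12 to 0.32, largest adjusted p = 2.63e-05). The proteasome list had 1 higher and 16 lower of 41 (1 and 18 adjusted over the list alone), a median of -0.31 and adjusted p = 0.00128. Members gave -1.24 for Rpn9, 0.77 for Rpn6, -1.01 for Prosbeta2 and -0.52 for Rpt2 (SE 0.10 to 0.14, largest adjusted p = 0.000931). Rpn6 went against the list and was not called without normalization (0.27). Mitochondrial respiration genes had 0 higher and 19 lower of 72 (0 and 21 adjusted over the list alone), a median of -0.17 and adjusted p = 0.000686. Members gave -0.99 for ND-MWFE, -0.39 for SdhC, -0.39 for UQCR-6.4 and -0.35 for ATPsynB (SE 0.07 to 0.12, largest adjusted p = 0.0012). The number of lower proteasome genes was 5 with only the compared groups in the fit and 10 with 1 variance factor per group, and that of lower mitochondrial genes ran from 6 in the former to 29 with median scaling. In a camera test on ranked limma statistics the proteasome shift was lost without replicate 3 of heat-shocked wild type (adjusted p = 0.0959 against 0.0363 with every array), and the mitochondrial respiration shift without replicate 1 (0.114 against 0.0346). These 4 lists, and the heat-inducible, chaperone and cuticle lists, also passed with an estimated correlation (largest adjusted p = 0.0379).

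Of midgut and digestive enzymes 9 higher and 4 lower of 36 (9 and 5 adjusted over the list alone) passed, with a median of 0.55 (adjusted p = 0.00763; adjusted p = 0.0606 with an estimated correlation), and 4 were higher without normalization. Members were 3.64 for Jon99Cii, 3.72 for Jon65Aiv and 1.30 for gammaTry (SE 0.16 to 0.27, largest adjusted p = 1.24e-05) besides Jon99Ciii, with Jon65Aiv at the floor in untreated embryos and gammaTry not called without normalization (0.80). For Hox genes and cofactors the counts were 2 higher and 0 lower of 8 (2 and 0 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.0433; adjusted p = 0.164 with an estimated correlation). The cofactor gene hth rose by 2.42 (SE 0.17, adjusted p = 2.18e-08) and Abd-B by 1.11 (SE 0.28, adjusted p = 0.00938), the latter not without normalization (0.65), with only the compared groups in the fit (adjusted p = 0.0564) or with 1 variance factor per group (adjusted p = 0.0507). Cell adhesion genes had 7 higher and 2 lower of 19 (7 and 2 adjusted over the list alone), with a median of 0.28 that became -0.19 without normalization, or 0.18 relative to all probe sets (adjusted p = 0.0208; adjusted p = 0.0614 with an estimated correlation). They included 1.25 for Fas3, 0.78 for fra, -1.16 for Toll-6 and 0.31 for Fas2 (SE 0.07 to 0.21, largest adjusted p = 0.00259); Fas3 and fra were not called without normalization (0.74 and 0.28), and Fas2 turned to -0.21 and was not called with median scaling (0.14). Cytosolic ribosomal proteins had 1 higher and 1 lower of 84 (0 and 1 adjusted over the list alone), a median of 0.11 and adjusted p = 0.0358 (adjusted p = 0.693 with an estimated correlation). Here RpS5b changed by -0.60 (SE 0.09, adjusted p = 0.000161) and RpS10a by 0.67 (SE 0.18, adjusted p = 0.0149), the latter not without replicate 2 of heat-shocked wild type (0.64, adjusted p = 0.0502), with median scaling (0.52), without normalization (0.17) or with only the compared groups in the fit (adjusted p = 0.129). With ranked limma statistics the ribosomal, Hox and adhesion shifts did not pass (adjusted p = 0.257, 0.0734 and 0.137).

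The 16 remaining lists did not pass, with camera adjusted p from 0.056 to 0.984. Higher and lower members were 3 and 0 of 15 for germ line and maternal, 0 and 3 of 6 for replication-dependent and variant histones and 2 and 0 of 10 for fat body and yolk. There were 6 and 2 of 21 for innate immunity, 3 and 4 of 22 for neuroblast and neural progenitor and 14 and 9 of 101 for glutathione transferases and cytochromes P450. There were 1 and 0 of 8 for apoptosis, 3 and 1 of 12 for glycolysis and 4 and 2 of 16 for haemocyte and basement membrane. There were 2 and 0 of 17 for blastoderm segmentation and early zygotic, 5 and 4 of 31 for sarcomere and muscle and 1 and 1 of 20 for head and brain patterning. There were 4 and 2 of 26 for neuronal and synaptic, 1 and 0 of 9 for trachea and 1 and 2 of 13 for glia. There were 2 and 4 of 18 for segment polarity with Hedgehog and Wnt. Adjusted over the list alone the counts were the same except 4 and 7 for neuroblast and neural progenitor, 14 and 10 for glutathione transferases and cytochromes P450, 0 and 0 for apoptosis, 3 and 2 for glycolysis, 5 and 2 for haemocyte and basement membrane, 4 and 1 for blastoderm segmentation and early zygotic, 6 and 4 for sarcomere and muscle, 0 and 0 for head and brain patterning and 5 and 5 for segment polarity with Hedgehog and Wnt. Median, mean and test differed in sign for neuronal and synaptic, glia, head and brain patterning, segment polarity, haemocyte, blastoderm segmentation and glycolysis genes.

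Without normalization the median of all probe sets was -0.36, and the share of changed probe sets that were higher was 14.7% without normalization and 35.1% with median scaling against 45.8%. The count of 2770 was 1289 without normalization, 1443 with only the compared groups in the fit and 1600 with 1 variance factor per group.

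**Figure D2:**
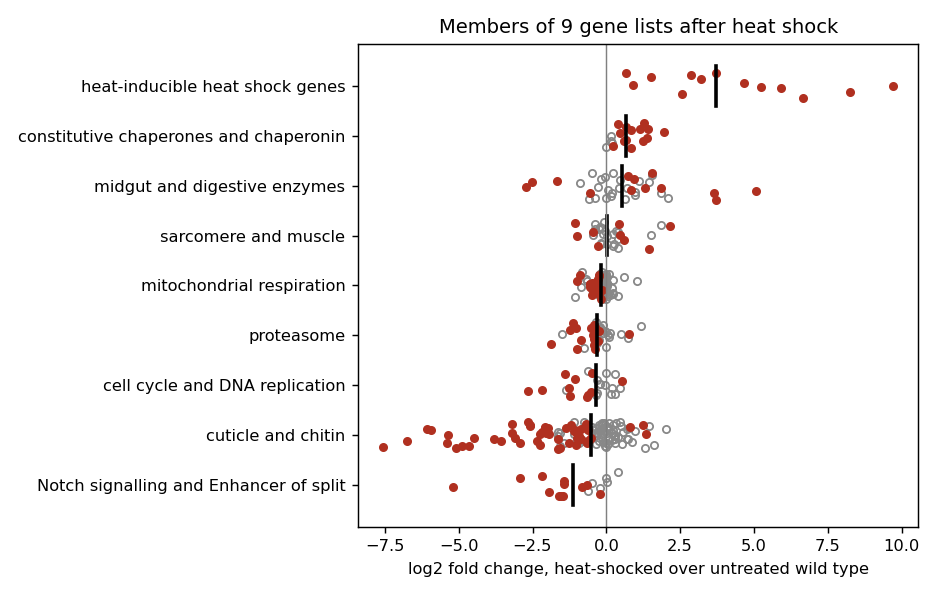
Log2 fold change of each measured member of 9 gene lists in heat-shocked over untreated wild type, filled where it passed, with a bar at the list median. The medians run from 3.73 in heat-inducible heat shock genes to -1.11 in Notch and Enhancer of split genes, and that of sarcomere and muscle genes, 0.01, becomes -0.25 without normalization.

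Heat-shocked hsp-otd (n = 4) and heat-shocked wild-type embryos (n = 3) were compared to ask which transcripts respond to otd. Besides oc, transcripts that were below the floor in heat-shocked wild type were measured in the hsp-otd line, among them PIG-O (5.09, SE 1.06, at least 34.1-fold, adjusted p = 0.00207) and GILT3 (4.84, SE 0.56, at least 28.7-fold, adjusted p = 1.31e-05). GILT3 was present in untreated wild type, from which hsp-otd did not differ (-0.32, adjusted p = 0.675). Drsl5, which encodes a drosomycin-like peptide, fell from 6795 to 191 (-5.16, SE 0.17, adjusted p = 6.78e-12). Genes of the Notch and Enhancer of split list and of the cell cycle rose, and sarcomere genes fell relative to the other probe sets. Of 12301 probe sets, 3610 (29.3%) passed, 1943 higher and 1667 lower, from 3124 named genes. Changes of at least 2-fold were found in 986 probe sets higher and 831 lower.

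Further high fold changes were 4.77 for Muc91C, 4.72 for nAChRalpha3, 4.71 for PIG-V, 4.70 for GckIII and 4.52 for Rca1 (SE 0.17 to 1.00, largest adjusted p = 0.00321), Muc91C at least 27.2-fold and nAChRalpha3 at least 26.3-fold, both from the floor. PIG-V, GckIII and Rca1 were above the floor in 1, 1 and 2 of 3 arrays of heat-shocked wild type, so their values depend on it, as does that of oc (2 of 3). Muc91C was lower than in untreated wild type (-2.29, adjusted p = 7.02e-09), against which PIG-V, Rca1 and Obp56e were not called (2.28, 1.70 and -1.15). The lowest, with oc at the other end, were -6.06 for jus, -5.69 for OtopLa, -4.81 for ftz, -4.57 for Zip42C.1, -4.17 for Ppn, -3.88 for Obp56e and -3.86 for pdm2 (SE 0.39 to 1.52, largest adjusted p = 0.00738). The named probe sets of OtopLa, jus and ftz were at the floor in hsp-otd, at least 51.5-fold, 66.5-fold and 28-fold lower. Zip42C.1, Ppn and Obp56e were above it in 2 of 4 hsp-otd arrays each and pdm2 in 3 of 4. Probe sets disagreed for pdm2, where another gave 1.15 (adjusted p = 0.0263) and a further one -0.76, and for OtopLa, where another, at a log2 level of 5.24 in hsp-otd, gave 0.57 (adjusted p = 0.42). Other probe sets of jus and Ppn gave -2.04 and -0.60, from log2 levels of 6.21 and 9.58 in hsp-otd.

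In the Notch signalling and Enhancer of split list 12 higher and 0 lower of 18 (12 and 0 adjusted over the list alone) passed, with a median of 1.06 (camera adjusted p = 4.03e-08). Among them were 1.45 for Ocho, 1.20 for E(spl)mgamma-HLH, 1.30 for Tom and 4.17 for E(spl)m5-HLH (SE 0.11 to 0.41, largest adjusted p = 2.57e-06), and the last was at least 18-fold higher. Against untreated wild type the list median in hsp-otd was -0.06, with 1 higher and 5 lower. Cell cycle and DNA replication genes had 17 higher and 0 lower of 25 (17 and 0 adjusted over the list alone), a median of 0.86 and adjusted p = 2.88e-09. Members gave 1.45 for PCNA, 1.11 for Mcm7, 1.21 for Cdk2 and 0.86 for fzy (SE 0.10 to 0.13, largest adjusted p = 1.26e-05); 11 were higher with array brightness as a covariate. Against untreated wild type the median was 0.43 with 10 higher and 0 lower, and PCNA and Cdk2 were not called (0.21 and -0.07). The proteasome list had 16 higher and 2 lower of 41 (16 and 2 adjusted over the list alone), a median of 0.35 and adjusted p = 0.000397, and the number higher ran from 7 with the brightness covariate to 30 without normalization. Members were 1.29 for Rpn9, 1.01 for Prosalpha1, 2.12 for Rpt6R and 2.70 for Prosbeta5 (SE 0.13 to 0.45, largest adjusted p = 0.000399), with Rpt6R at least 4.35-fold higher. Rpt6R was also above the floor in every hsp-Otx2 array and at it in untreated wild type, so it parts both lines from Oregon-R. The proteasome median against untreated wild type was 0.08 with 6 higher and 5 lower, and Rpn9 and Prosbeta5 were not called (0.05 and 0.82). Sarcomere and muscle genes had 1 higher and 15 lower of 31 (1 and 15 adjusted over the list alone), with a median of -0.46 that became 0.28 without normalization, where 2 were lower, or -0.39 relative to all probe sets (adjusted p = 6.51e-05). Members were -1.25 for Prm, -0.60 for Actn, -0.90 for up and -0.90 for Zasp52 (SE 0.07 to 0.14, largest adjusted p = 0.000243), and without normalization none of these was called, at -0.32, 0.22, -0.02 and 0.02. These 4 lists also passed with an estimated correlation (largest adjusted p = 0.0125).

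The list of cytosolic ribosomal proteins had 7 higher and 32 lower of 84 (11 and 38 adjusted over the list alone), a median of -0.25 and adjusted p = 0.00265, or adjusted p = 0.486 with an estimated correlation. Members were 0.85 for RpS5b, -0.70 for RpL32, 1.29 for RpL7-like and -0.96 for RpS3 (SE 0.09 to 0.23, largest adjusted p = 0.00136). The lower count was 9 without normalization, 14 with eBayes without a trend and 2 with array brightness as a covariate. It rested on single arrays too: it was 11 without hsp-otd replicate 3, 15 without hsp-otd replicate 4, 17 without replicate 1 of heat-shocked wild type and 11 without its replicate 3. The list of replication-dependent and variant histones had 3 higher and 0 lower of 6 (3 and 0 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.0272; adjusted p = 0.24 with an estimated correlation). Members gave 1.03 for His2B:CG17949, 0.48 for His2Av and 0.71 for His3.3A (SE 0.07 to 0.13, largest adjusted p = 0.000988). With ranked limma statistics the histone shift was lost with median scaling (adjusted p = 0.0756) and the ribosomal shift with array brightness as a covariate (adjusted p = 0.949). The head and brain patterning list, for the part of the embryo where otd acts in normal development, did not pass, with 3 higher and 2 lower of 20 (3 and 2 adjusted over the list alone), a median of 0.06 and adjusted p = 0.982. With oc, the transgene itself, left out, a test chosen after the data were seen, 2 were higher and 2 lower of 19 and adjusted p = 0.683. Besides oc the called members were 0.88 for hbn, -1.95 for Rx and 1.47 for scro (SE 0.24 to 0.54, largest adjusted p = 0.0219), and Lim1 (-0.39, SE 0.14, adjusted p = 0.0426), which the rule for named genes leaves out and which was chosen after its values were seen. The call of hbn was lost without replicate 3 of heat-shocked wild type (0.61, adjusted p = 0.0713) and with only the compared groups in the fit (adjusted p = 0.0538), and that of Rx without replicate 1 (-1.65, adjusted p = 0.0533) and without normalization (-1.36, adjusted p = 0.0615). The call of scro was lost without hsp-otd replicate 3 (1.41, adjusted p = 0.0512) or replicate 3 of heat-shocked wild type (1.37, adjusted p = 0.0659), with a floor of 5 (adjusted p = 0.0581) and with a generalized log (1.38, adjusted p = 0.0544). Rx was above the floor in 1 of 4 hsp-otd arrays. None of hbn, Rx, scro and His3.3A was called against untreated wild type (0.46, -0.82, 0.68 and 0.30). Cuticle and chitin genes went both ways, with 27 higher and 16 lower of 117 (27 and 17 adjusted over the list alone), a median of 0.00, a mean of 0.24 and adjusted p = 0.549. Without normalization 45 were higher and 2 lower with a median of 0.77, and with array brightness as a covariate 17 were higher. Those higher than in heat-shocked wild type included 2.73 for Cpr65Ea, 3.55 for TwdlW, 3.61 for Ccp84Ac and 4.20 for TwdlV (SE 0.09 to 0.27, largest adjusted p = 2.17e-08), the last 3 at least 11.7-fold, 12.2-fold and 18.4-fold. All 4 were lower than in untreated wild type, by log2 fold changes of -2.35, -4.0, -3.13 and -1.89.

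The 19 remaining lists did not pass and gave camera adjusted p from 0.051 to 0.995. Higher and lower members were 1 and 7 of 16 for haemocyte and basement membrane, 9 and 15 of 72 for mitochondrial respiration and 0 and 4 of 17 for blastoderm segmentation and early zygotic. There were 7 and 2 of 18 for constitutive chaperones and chaperonin, 0 and 3 of 12 for glycolysis and 0 and 1 of 10 for fat body and yolk. There were 3 and 7 of 36 for midgut and digestive enzymes, 2 and 5 of 26 for neuronal and synaptic and 5 and 2 of 18 for segment polarity with Hedgehog and Wnt. There were 0 and 1 of 8 for Hox genes and cofactors, 14 and 16 of 101 for glutathione transferases and cytochromes P450 and 4 and 2 of 22 for neuroblast and neural progenitor. There were 5 and 3 of 15 for germ line and maternal, 3 and 1 of 13 for glia and 2 and 2 of 21 for innate immunity. There were 0 and 1 of 8 for apoptosis, 0 and 2 of 13 for heat-inducible heat shock genes and 1 and 0 of 9 for trachea. There were 4 and 2 of 19 for cell adhesion. Adjusted over the list alone the counts were the same except 10 and 22 for mitochondrial respiration, 10 and 3 for constitutive chaperones and chaperonin, 0 and 0 for fat body and yolk, 3 and 5 for neuronal and synaptic and 0 and 1 for heat-inducible heat shock genes. Median, mean and test differed in sign for heat-inducible, germ line, glycolysis and adhesion genes.

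With array brightness as a covariate, chosen after the data were seen, 1389 probe sets passed, and PIG-O, PIG-V, GckIII, Rca1, jus, Zip42C.1, Ppn, Obp56e, hbn, Rx and scro did not. Without normalization all probe sets shifted by a median of 0.68 and 92.8% of changed ones were higher, and with median scaling these values were 0.16 and 71.7%, against 53.8%.

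Heat-shocked hsp-Otx2 (n = 4) and heat-shocked wild-type embryos (n = 3) were compared to ask which fly transcripts respond to human Otx2. The list of transcripts with the highest fold changes held several at the floor in heat-shocked wild type: CR14033 was at least 121-fold higher (6.91, SE 0.29, adjusted p = 1.05e-10), and dhd, a maternal thioredoxin gene, at least 63.9-fold (6.0, SE 0.52, adjusted p = 2.09e-07). CR14033 was also above the floor in every hsp-otd array and at it in untreated wild type, so it parts both lines from Oregon-R. Jon99Fi, a Jonah digestive protease gene, was above the floor in 1 of 3 arrays of heat-shocked wild type and rose to 3748 (5.47, SE 1.08, adjusted p = 0.000834). Drsl5 fell from 6795 to 108 (-5.97, SE 0.17, adjusted p = 9.37e-13), as it did in hsp-otd. Of 12301 probe sets, 4577 (37.2%) passed, 2154 higher and 2423 lower, from 3939 named genes. Changes of at least 2-fold were found in 1461 probe sets higher and 1040 lower, and the median of all probe sets was -0.13.

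Others with high fold changes were 6.19 for lic, 6.09 for muskelin, 6.07 for flfl, 5.75 for Jon25Bi, 5.59 for Mal-A4 and 5.49 for Vps26 (SE 0.33 to 0.78, largest adjusted p = 2.53e-05). In heat-shocked wild type lic, flfl, Jon25Bi, Mal-A4 and Vps26 were at the floor, so they were at least 72.8-fold, 67.3-fold, 53.9-fold, 48.3-fold and 44.8-fold higher, and muskelin was above it in 1 of 3 arrays. Like CR14033, flfl and Vps26 were above the floor in every hsp-otd array and at it in untreated wild type. The lowest fold changes after Drsl5 were -5.32 for eyg, -4.33 for Sgsh, -4.28 for ftz, -4.26 for Ppn, -4.20 for GstE13, -4.15 for Ncoa6 and -4.14 for hang (SE 0.19 to 0.99, largest adjusted p = 0.00284), with GstE13 at least 18.3-fold lower. In hsp-Otx2 eyg, Sgsh and hang were above the floor in 2 of 4 arrays and ftz, Ppn and Ncoa6 in 1 of 4, so these values depend on it. Another probe set of hang gave 1.36 (adjusted p = 7e-08), against the direction of the named one, and another of Ppn gave -0.28 and did not pass.

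Notch signalling and Enhancer of split genes had 1 higher and 11 lower of 18 (1 and 11 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.000419; adjusted p = 0.112 with an estimated correlation), and 4 were lower without normalization. Among the lower genes were -1.45 for Brd, -1.96 for E(spl)m4-BFM, -1.81 for E(spl)m7-HLH and -0.91 for E(spl)mbeta-HLH (SE 0.07 to 0.13, largest adjusted p = 5.97e-08), the last of them not called without normalization (-0.30). Against untreated wild type the median was -2.32, with 1 higher and 13 lower. Midgut and digestive enzymes had 14 higher and 2 lower of 36 (14 and 2 adjusted over the list alone), with a median of 0.57 (adjusted p = 0.00274; adjusted p = 0.112 with an estimated correlation). Members gave 1.30 for Npc2a, 1.77 for alphaTry and 2.03 for gammaTry (SE 0.09 to 0.16, largest adjusted p = 8.94e-08). Of cell cycle and DNA replication genes 12 higher and 6 lower of 25 (13 and 6 adjusted over the list alone) passed, with a median of 0.60 (adjusted p = 0.0322; adjusted p = 0.112 with an estimated correlation). Members gave 2.26 for CycB, 2.86 for polo, 1.39 for Mcm7 and 1.23 for fzy (SE 0.10 to 0.20, largest adjusted p = 9.34e-08). The cell cycle list over untreated wild type had 9 higher and 12 lower, with a median of 0.19, so its balance turns with the control. Blastoderm segmentation and early zygotic genes had 0 higher and 7 lower of 17 (0 and 8 adjusted over the list alone), with a median of -0.91 (adjusted p = 0.0476; adjusted p = 0.176 with an estimated correlation). Besides ftz they included -1.08 for eve and -0.91 for odd (SE 0.14 each, largest adjusted p = 9.85e-05) and were not called without normalization (-0.44 and -0.41), where 1 gene of the list was lower. Histones had 3 higher and 0 lower of 6 (5 and 0 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.0299; adjusted p = 0.141 with an estimated correlation), and the called ones were 0.74 for His2Av, 1.71 for BigH1 and 0.26 for His4r (SE 0.07 to 0.50, largest adjusted p = 0.0342). His4r was not called without hsp-Otx2 replicate 3 (0.21, adjusted p = 0.0968) or 4 (0.26, adjusted p = 0.0645), or without replicate 1 (0.27, adjusted p = 0.0576) or 3 (0.19, adjusted p = 0.153) of heat-shocked wild type. It was also not called with median scaling (0.06, adjusted p = 0.784), without normalization (0.41, adjusted p = 0.154) or with array brightness as a covariate (0.11, adjusted p = 0.204). The same held with only the compared groups in the fit, array weights, eBayes without a trend and 1 variance factor per group (adjusted p = 0.0626, 0.074, 0.099 and 0.0702).

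The medians of 3 more lists turned without normalization. Constitutive chaperones and chaperonin had 0 higher and 12 lower of 18 (1 and 12 adjusted over the list alone), with a median of -0.36 against 0.17 without normalization, or -0.11 relative to all probe sets (adjusted p = 0.00807; adjusted p = 0.141 with an estimated correlation). Members were -0.51 for Cnx99A, -0.43 for CCT8, -0.48 for Gp93 and -0.67 for CCT7 (SE 0.06 to 0.12, largest adjusted p = 0.000276), and without normalization they were -0.03, 0.12, 0.04 and -0.04, none of them called. With median scaling CCT8, Gp93 and CCT7 were not called either (-0.23, -0.31 and -0.38). The chaperone median against untreated wild type was 0.21 with 9 higher and 2 lower, CCT8 was higher (0.24, adjusted p = 0.00225) and CCT7 did not differ (0.00). Mitochondrial respiration genes had 5 higher and 30 lower of 72 (6 and 30 adjusted over the list alone), with a median of -0.24 against 0.30 without normalization, where 5 were higher and 0 lower, or 0.01 relative to all probe sets (adjusted p = 0.0286; adjusted p = 0.141 with an estimated correlation). They included -0.63 for ND-PDSW, 0.80 for Cyt-c-p, -0.86 for ND-ACP and -0.69 for ND-B12 (SE 0.06 to 0.12, largest adjusted p = 3.77e-05), and of these ND-PDSW, ND-ACP and ND-B12 were not called without normalization (0.00, -0.26 and -0.08). Cell adhesion genes had 1 higher and 9 lower of 19 (1 and 9 adjusted over the list alone), with a median of -0.38 against 0.21 without normalization, or -0.08 relative to all probe sets (adjusted p = 0.0299; adjusted p = 0.135 with an estimated correlation). The lower ones included -1.12 for Fas2, -0.46 for Nrt, -0.34 for Nrg and -0.98 for Toll-6 (SE 0.07 to 0.22, largest adjusted p = 0.00212), and without normalization they were -0.47, 0.18, 0.29 and -0.53, none of them called, while with median scaling Nrt and Nrg were not (-0.17 and -0.06). The adhesion list over untreated wild type had 4 higher and 5 lower, with a median of 0.03. With ranked limma statistics the chaperone and adhesion shifts were lost without replicate 1 of heat-shocked wild type (adjusted p = 0.06 each), the mitochondrial respiration shift without its replicate 3 (adjusted p = 0.0539), and those of histones and blastoderm genes with every array present (adjusted p = 0.064 and 0.067).

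Head and brain patterning genes did not pass as a list, with 0 higher and 9 lower of 20 (0 and 11 adjusted over the list alone), a median of -0.67 and adjusted p = 0.0825. Members called were -1.08 for slp1, -2.17 for Rx, -0.96 for btd and -0.71 for slp2 (SE 0.20 to 0.54, largest adjusted p = 0.01), and without normalization none of them was (-0.58, -1.44, -0.54 and -0.28). Cuticle and chitin genes again went both ways, with 18 higher and 25 lower of 117 (18 and 27 adjusted over the list alone), a median of -0.20 and adjusted p = 0.902, and the lower count was 15 without replicate 3 of heat-shocked wild type and 13 with array brightness as a covariate. Without normalization it was 0, with 23 higher and a median of 0.26. The higher ones included 5.21 for Ccp84Ac, 3.93 for TwdlW and 1.26 for TwdlF (SE 0.10 to 0.19, largest adjusted p = 8.63e-08), and these were lower than in untreated wild type, at -1.53, -3.62 and -1.01. Cpr, at 1.29 (SE 0.12, adjusted p = 5.39e-07), encodes cytochrome P450 reductase and stood in this list through its symbol alone.

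The 17 remaining lists did not pass and gave camera adjusted p from 0.0709 to 0.93. Higher and lower members were 0 and 9 of 16 for haemocyte and basement membrane, 5 and 1 of 15 for germ line and maternal and 0 and 5 of 8 for Hox genes and cofactors. There were 2 and 9 of 22 for neuroblast and neural progenitor, 0 and 4 of 13 for glia and 5 and 1 of 21 for innate immunity. There were 2 and 7 of 26 for neuronal and synaptic, 2 and 1 of 8 for apoptosis and 3 and 1 of 84 for cytosolic ribosomal proteins. There were 0 and 1 of 10 for fat body and yolk, 1 and 8 of 31 for sarcomere and muscle and 0 and 3 of 9 for trachea. There were 16 and 21 of 101 for glutathione transferases and cytochromes P450, 1 and 2 of 13 for heat-inducible heat shock genes and 11 and 15 of 41 for proteasome. There were 3 and 4 of 18 for segment polarity with Hedgehog and Wnt and 2 and 3 of 12 for glycolysis. Adjusted over the list alone the counts were the same except 2 and 9 for haemocyte and basement membrane, 3 and 9 for neuroblast and neural progenitor, 2 and 6 for neuronal and synaptic, 0 and 0 for fat body and yolk, 16 and 19 for glutathione transferases and cytochromes P450 and 12 and 15 for proteasome. Median, mean and test differed in sign for glycolysis genes. In this and the other comparisons, leaving out 1 array moved many of the counts under 10 by over 1.5 times. Such counts are uncertain, also for the lists described through them.

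No list shift of this comparison passed with an estimated correlation. Without normalization 2378 probe sets passed, 86.4% of them higher, with a median of all probe sets of 0.29, and with median scaling 60.5% were higher, against 47.1%.

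The responses to otd and Otx2 were set side by side to ask how many transcripts changed in both lines. Muc91C rose in both lines, by 4.77 in hsp-otd (SE 0.17, n = 4) and 5.06 in hsp-Otx2 (SE 0.17, n = 4), at least 27.2-fold and 33.4-fold over the floor in heat-shocked wild type. Against untreated wild type Muc91C was lower in both, at -2.29 and -2.0 (adjusted p = 7.02e-09 and 1.83e-08), so its direction turns with the control. Drsl5 and the pair-rule gene ftz fell in both, with -5.16 and -5.97 for Drsl5 and -4.81 and -4.28 for ftz (SE 0.17, 0.17, 0.74 and 0.74). Both lines raised 999 probe sets and lowered 976, which together are 54.7% of the changes in hsp-otd and 43.2% of those in hsp-Otx2. Another 255 probe sets passed in opposite directions, 202 of them higher in hsp-otd and lower in hsp-Otx2 and 53 the other way.

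In each pair below the value of hsp-otd comes before that of hsp-Otx2. The other shared genes with the highest fold changes were 4.97 and 5.08 for CG12391, 4.75 and 5.88 for CG4768, 4.71 and 4.66 for PIG-V, 4.53 and 5.34 for CG1951 and 4.23 and 4.17 for CG18004. The SEs of these genes ran from 0.70 to 0.95. CG12391, CG4768, CG1951 and CG18004 were at the floor in heat-shocked wild type, so the hsp-otd changes were at least 31.4-fold, 26.9-fold, 23.1-fold and 18.8-fold. The lowest shared values besides Drsl5 and ftz were -4.85 and -4.85 for CG32432, -4.85 and -4.85 for CG33253, -4.17 and -4.26 for Ppn and -3.88 and -3.97 for Obp56e, with SEs from 0.50 to 0.99. The named probe sets of CG32432 and CG33253 were at the floor in both lines, at least 28.9-fold and 28.9-fold lower. Their other probe sets did not pass, and that of CG33253 lay well above the floor, at log2 levels of 9.06 and 9.53 in the lines and 9.42 in untreated wild type. The named one of CG33253 was at the floor in untreated wild type too, against which Obp56e was not called in either line (-1.15 and -1.23) nor CG1951 in hsp-otd (1.59). Values partly at the floor were those of PIG-V (above it in 1 of 3 control arrays), and of Ppn and Obp56e (2 of 4 in hsp-otd and 1 of 4 in hsp-Otx2). With array brightness as a covariate CG4768 and CG32432 were not called in hsp-otd (2.81 and -2.84).

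Independent sets of these sizes would share 340.2 probe sets raised and 328.4 lowered, and 100 simulations of unchanged groups against the same 3 control arrays shared a mean of 0, a value for chance without any effect. The fold changes of the lines correlated across probe sets, which are not independent replicates, at r = 0.642 against a simulated 0.572, with a covariance of 0.785 against 0.131, and 72.1% against 69.4% had the same sign. The simulation gave all groups the same spread, but the median SD was 0.382 in heat-shocked wild type, 0.206 in hsp-otd and 0.229 in hsp-Otx2. A noisier shared control raises r, the covariance and the share of same signs by itself, so no excess is drawn from any of them. With no array in common, 683 probe sets were higher and 558 lower in both of hsp-otd over heat-shocked and hsp-Otx2 over untreated wild type, and 728 and 593 when the controls were exchanged. Of the 1975 shared probe sets, 1448 were not called between the lines. Another overlap is with heat-shocked over untreated wild type, where 829 of the 1975 changed, 765 of them in the opposite direction. The heat-shocked wild-type arrays enter these contrasts with opposite signs, so noise in them gives opposite directions by itself. Part of the overlap may come from these shared control arrays, which at n = 3 cannot be split, and 746 shared changes were left with array brightness as a covariate.

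**Figure D3:**
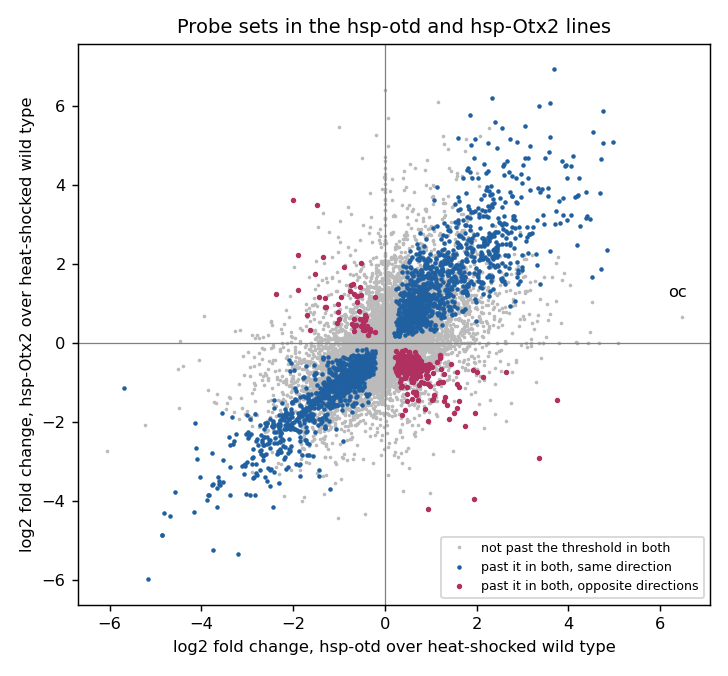
Log2 fold change of each tested probe set in hsp-otd (x axis) and in hsp-Otx2 (y axis), both over heat-shocked wild type. The 1975 probe sets changed in the same direction and the 255 in opposite directions are coloured, and oc stands alone at 6.47 and 0.65.

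The lines were compared directly, with no wild-type array in the contrast, to ask where otd and Otx2 embryos differ. Enhancer of split and Bearded family genes were higher in hsp-otd: E(spl)m4-BFM was 2304 against 310.1 (2.89, SE 0.12, adjusted p = 5.67e-11) and Brd 2263 against 498 (2.19, SE 0.09, adjusted p = 3.53e-11), with n = 4 in each line. Digestive protease genes were higher in hsp-Otx2: Jon99Ciii was 243 against 7577 (-4.96, SE 0.42, adjusted p = 1.41e-07). Of 12301 probe sets 3630 (29.5%) differed, 1935 higher and 1695 lower in hsp-otd, from 3194 named genes. The difference was at least 2-fold for 757 probe sets higher and 918 lower.

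Besides oc, the highest in hsp-otd were 5.89 for Rdh1, 5.2 for Uhg1, 5.14 for GstE13 and 5.09 for PIG-O (SE 0.17 to 0.98, largest adjusted p = 0.000732), of which Uhg1, GstE13 and PIG-O were at the floor in hsp-Otx2 and so at least 36.7-fold, 35.4-fold and 34.1-fold higher, and Rdh1 was above it in 1 of 4 arrays. The highest in hsp-Otx2, besides Jon99Ciii, had values of -6.46 for Jon99Fi, -5.46 for mol, -5.15 for Trf2 and -4.93 for muskelin (SE 0.37 to 1.00, largest adjusted p = 9.28e-05). In hsp-otd mol and Trf2 were above the floor in 1 of 4 arrays and Jon99Fi and muskelin in 3 of 4. Other probe sets of mol and Trf2 gave -2.53 and -3.96.

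The Notch signalling and Enhancer of split list had 14 higher and 0 lower of 18 (14 and 0 adjusted over the list alone), with a median of 2.04 (camera adjusted p = 5.08e-13). Besides Brd and E(spl)m4-BFM it held 2.18 for E(spl)mgamma-HLH and 2.19 for E(spl)m7-HLH (SE 0.10 to 0.11, largest adjusted p = 6.54e-10). Midgut and digestive enzymes had 1 higher and 16 lower of 36 (1 and 17 adjusted over the list alone), with a median of -0.89 and adjusted p = 3.98e-06. Members gave -2.56 for gammaTry, -1.87 for alphaTry and -3.52 for Jon99Cii (SE 0.13 to 0.24, largest adjusted p = 1.18e-08). For constitutive chaperones and chaperonin the counts were 11 higher and 1 lower of 18 (11 and 1 adjusted over the list alone), with a median of 0.59 and adjusted p = 0.000172, and members were 0.82 for Cnx99A, 0.97 for Gp93, 0.60 for CCT8 and 0.83 for CCT4 (SE 0.06 to 0.09, largest adjusted p = 1.5e-06). The proteasome had 19 higher and 6 lower of 41 (20 and 6 adjusted over the list alone), with a median of 0.70 and adjusted p = 0.00334; Prosbeta7 went against it, and values were -0.99 for Prosbeta7, 0.86 for Rpn3, 0.83 for Rpn7 and 0.79 for Rpt3 (SE 0.07 each, largest adjusted p = 5.15e-07). Prosbeta7 was not called without normalization (-0.64, adjusted p = 0.0879). Neuroblast and neural progenitor genes had 9 higher and 1 lower of 22 (11 and 1 adjusted over the list alone), with a median of 0.79 and adjusted p = 0.0105. Members gave 1.89 for mira, 1.13 for l(1)sc, 2.15 for pdm2 and 0.72 for pros (SE 0.15 to 0.34, largest adjusted p = 0.00111). For pdm2 this is the probe set that gave 1.15 in hsp-otd, while another went the other way (-2.67, adjusted p = 0.000411) and a further one gave -0.08. In this list pros was not called without normalization (0.98, adjusted p = 0.0625). Head and brain patterning genes had 7 higher and 0 lower of 20 (7 and 0 adjusted over the list alone), with a median of 0.68 and adjusted p = 0.0198, and besides oc they were led by 0.91 for slp2, 1.29 for ems and 0.75 for slp1 (SE 0.18 to 0.34, largest adjusted p = 0.00803), with slp1 not called without normalization (1.02, adjusted p = 0.0531). With oc left out, again chosen after the data were seen, 6 were higher of 19 with a median of 0.62, and the list did not pass (adjusted p = 0.057). Sarcomere and muscle genes had 1 higher and 12 lower of 31 (1 and 12 adjusted over the list alone), with a median of -0.27 that became 0.00 without normalization, where 0 were lower, or -0.26 relative to all probe sets (adjusted p = 0.0036). Members were -0.96 for Prm, -0.54 for Mf, -0.93 for up and -0.65 for Tm1 (SE 0.07 to 0.12, largest adjusted p = 2.7e-05), none of them called without normalization. These 7 lists also passed with an estimated correlation (largest adjusted p = 0.0457), but with oc left out the head and brain, chaperone and neuroblast lists did not (adjusted p = 0.0791, 0.0518 and 0.0532). Cell adhesion genes had 8 higher and 1 lower of 19 (8 and 2 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.0205; adjusted p = 0.064 with an estimated correlation). Members gave 2.24 for Toll-6, 0.99 for Fas2, 0.75 for Nrg and 0.89 for Nrt (SE 0.06 to 0.20, largest adjusted p = 5.63e-07). With ranked limma statistics the shifts of the neuroblast and neural progenitor list and of the head and brain patterning list did not pass (adjusted p = 0.0553 and 0.0702).

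The other 19 lists did not pass, with camera adjusted p from 0.0591 to 0.999. Higher and lower members were 6 and 8 of 84 for cytosolic ribosomal proteins, 4 and 1 of 13 for glia and 13 and 8 of 25 for cell cycle and DNA replication. There were 1 and 4 of 21 for innate immunity, 18 and 6 of 72 for mitochondrial respiration and 4 and 0 of 9 for trachea. There were 2 and 4 of 15 for germ line and maternal, 5 and 3 of 18 for segment polarity with Hedgehog and Wnt and 2 and 4 of 12 for glycolysis. There were 4 and 1 of 17 for blastoderm segmentation and early zygotic, 2 and 0 of 8 for Hox genes and cofactors and 20 and 11 of 117 for cuticle and chitin. There were 1 and 1 of 8 for apoptosis, 15 and 19 of 101 for glutathione transferases and cytochromes P450 and 0 and 1 of 10 for fat body and yolk. There were 6 and 4 of 16 for haemocyte and basement membrane, 2 and 2 of 6 for replication-dependent and variant histones and 2 and 1 of 13 for heat-inducible heat shock genes. There were 5 and 3 of 26 for neuronal and synaptic. Adjusted over the list alone the counts were the same except 4 and 5 for cytosolic ribosomal proteins, 5 and 1 for glia, 0 and 0 for fat body and yolk and 2 and 3 for replication-dependent and variant histones. Median, mean and test differed in sign for heat-inducible, neuronal and apoptosis genes.

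Each transgene was carried by 1 line, so effects of a transgene and of its line were not separated. Without normalization 1837 probe sets passed, 71.0% of them higher, with a median of all probe sets of 0.26, and with median scaling 57.1% were higher, against 53.3%.

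**Figure D4:**
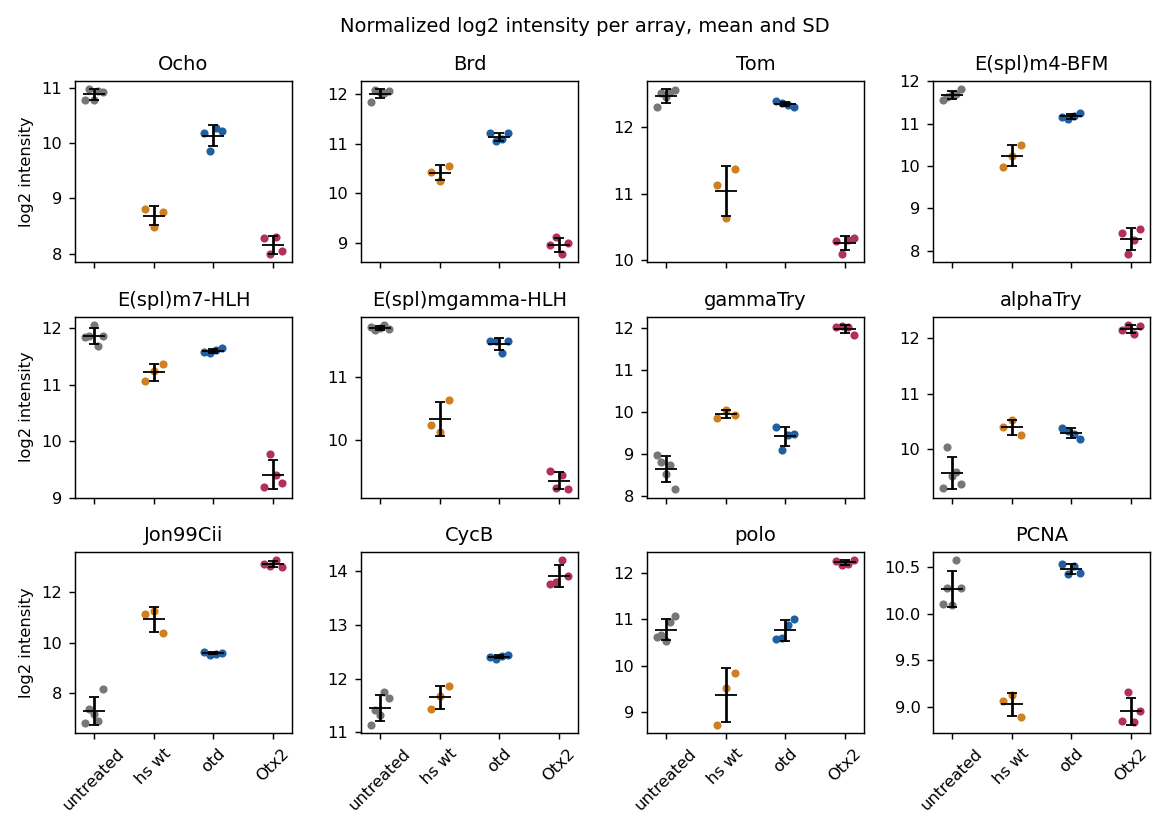
Log2 normalized intensity of 12 genes in each array of the 4 groups, with the group mean and SD as lines. Ocho, Brd, Tom and the 3 Enhancer of split genes are lower in every hsp-Otx2 array than in any other array, and gammaTry, alphaTry, Jon99Cii, CycB and polo are higher.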

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

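The tests of dimmer arrays, a younger mix of embryos and heat shock itself for the cuticle genes, those of shared control arrays, array brightness and embryo age for the Notch genes, and the test without oc, were chosen after the results were seen; those of signal near the floor and genetic background were not.

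Cuticle and chitin genes were lower after heat shock in wild type, 48 of 117, with genes such as TwdlW and Cpr65Ea. Dimmer arrays are argued against: the lowest untreated array still had a list median 0.69 log2 above that of the highest hsp-otd array, and every hsp-otd array was brighter in the mean than untreated replicates 1 to 3. Heat shock itself may lower these transcripts, since 43 genes of the list were lower than in untreated embryos in all 3 heat-shocked groups, but these contrasts share the untreated arrays. A younger mix of embryos stays open, since muscle genes, which would fall with it, went both ways around a median of 0.01. Midgut and digestive enzymes, which would fall too, had 9 higher and 4 lower of 36, with a median of 0.55. That rise did not pass in camera with an estimated correlation (adjusted p = 0.0606). The untreated embryos as a separate batch cannot be told apart from the treatment either, since the labels give no shared collection.

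Notch signalling and Enhancer of split genes were higher in hsp-otd and lower in hsp-Otx2 than in heat-shocked wild type, the latter with adjusted p = 0.112 with an estimated correlation and 4 instead of 11 lower genes without normalization; against untreated wild type the medians were -0.06 and -2.32, so a rise in hsp-otd shows only against heat-shocked wild type. Array brightness is argued against for the difference between the lines, since 14 genes were also higher in hsp-otd than in hsp-Otx2 with brightness in the fit. It stays open for the shifts from heat-shocked wild type, which that contrast leaves out. Array means there were 460.2 to 650.2, against 785.9 to 997.8 in hsp-otd. Shared control arrays stay open for the shifts from heat-shocked wild type too, since noise in them moves both fold changes the same way. The contrast between the lines, with 14 genes higher and 0 lower of 18, uses no control array, so it cannot test them. The position of heat-shocked wild type between the lines still rests on its 3 arrays. Younger embryos in the hsp-otd collection stay open, since cuticle genes went both ways around a median of 0.16 between the lines. Muscle and midgut genes were lower in hsp-otd (12 and 16 lower, 1 higher each), as this needs. Germ line and maternal genes had 2 higher and 4 lower of 15 in hsp-otd, with a median of -0.28, the opposite of what it needs. That list did not pass (camera adjusted p = 0.227). An action of the proteins on the Notch and Enhancer of split genes was not tested and stays open too, with 1 line per protein.

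Some probe sets parted both transgenic lines from both Oregon-R groups, being above the floor in every array on one side and at it in every array on the other. There were 19 of them, against 1 and 2 for the other pairings of the groups, and 18 were present in the transgenic lines, among them CR14033, flfl and Vps26. Signal near the floor is argued against for most of them by a median level of 136.4 on the present side, well above 20. Levels ran from 45.9 for rdo to 790.8 for CR14033, so it stays open for the lowest. The floor is a chosen value and not a measured noise level. The genetic background of the lines may explain these probe sets, but it cannot be told apart from a common effect of both proteins, since no line without a transgene in the same background was profiled.

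In 56 groups of values tested for a single array far from the rest, chance would mark about 1 in 20. The mean deposited intensity of hsp-otd replicate 1 was 785.9 against 969.7 to 997.8 in the others. In log2 intensity, Ccp84Ac was 10.47 in untreated replicate 3 against 11.15 to 11.25, and PIG-O was 8.44 in hsp-otd replicate 2 against 9.66 to 9.81. Mal-A4 was 10.69 in hsp-Otx2 replicate 2 against 9.62 to 9.73, and CG12391 was 8.87 there against 9.52 to 9.65. CG1951 was 8.08 in hsp-otd replicate 2 against 9.06 to 9.16, and CG18004 was 8.18 in hsp-otd replicate 3 against 8.65 to 8.69.

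The lines differed, by the direct contrast, in 7 lists that pass with an estimated correlation, without a separation of protein and line. With oc left out, the head and brain patterning list did not pass (adjusted p = 0.057), and the chaperone and neuroblast lists did not with an estimated correlation (adjusted p = 0.0518 and 0.0532). With ranked limma statistics the neuroblast and neural progenitor list and the head and brain patterning list did not pass (adjusted p = 0.0553 and 0.0702). Median log2 fold changes of hsp-otd over hsp-Otx2 were 2.04 for Notch and Enhancer of split genes, -0.89 for midgut enzymes, 0.59 for chaperones, 0.70 for the proteasome, 0.79 for neuroblast genes, 0.68 for head and brain patterning genes and, with 0.00 without normalization, -0.27 for sarcomere and muscle genes. The 255 probe sets that passed in opposite directions in the lines all differed in the direct contrast, which their selection on opposite sides of 1 control fixes.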

How the results depend on the processing

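The fits with array brightness as a covariate, with untreated wild type reduced to replicates 1 to 3, with 1 variance factor per group and with oc left out of the lists were tests chosen after the results were seen. Of 207 values of named genes, 166 kept direction and call without normalization, 34 lost the call and 7 reversed; with median scaling 199 kept both and 8 lost the call, and with the brightness covariate these numbers were 193 and 14. In the other settings run on all arrays with the same control, at least 202 kept both. Without single arrays no named value reversed.

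The counts of changed probe sets were 2770 for heat shock, 3610 for hsp-otd, 4577 for hsp-Otx2, 3630 between the lines and 1975 shared. Without normalization they moved to 1289 for heat shock, 2378 for hsp-Otx2 and 1837 between the lines. With only the compared groups in the fit heat shock gave 1443, and with 1 variance factor per group 1600. The brightness covariate left 1389 for hsp-otd and 746 shared. The cause was not tested for any of these. At an adjusted p below 0.01, which by construction passes fewer, the counts were 1571 for heat shock, 1993 for hsp-otd, 3048 for hsp-Otx2 and 1012 shared. Shared changes numbered 1241 when hsp-otd was set against heat-shocked and hsp-Otx2 against untreated wild type, which removes the shared arrays and adds the effect of heat shock.

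Leaving out 1 array gave 2303 to 2940 for heat shock, 2845 to 3656 for hsp-otd, 3895 to 4527 for hsp-Otx2, 3178 to 3270 between the lines and 1476 to 2128 shared, each within 1.5 times the full count. The lowest for hsp-otd, hsp-Otx2 and the shared changes came without replicate 3 of heat-shocked wild type.

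Fitting the replicate number as a block gave 2166 for heat shock, 3171 for hsp-otd, 4264 for hsp-Otx2, 3587 between the lines and 1734 shared. Of the named genes, Abd-B after heat shock, scro in hsp-otd and His4r in hsp-Otx2 did not pass under the block (adjusted p = 0.0502, 0.0635 and 0.0707). Deviations of same-numbered arrays from their group means correlated at a mean r of 0.005 (21 pairs, from -0.071 to 0.115), and those of different numbers at -0.001 (74 pairs), and not every array correlated best with one of its own number, so the numbers do not pair the arrays.

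Without normalization 7 values reversed: Fas2 after heat shock (-0.21), Actn (0.22) and Zasp52 (0.02) in hsp-otd, and CCT8 (0.12), Gp93 (0.04), Nrt (0.18) and Nrg (0.29) in hsp-Otx2. The shift of all probe sets that this setting leaves in (-0.36, 0.68 and 0.29) has the sign of each reversal.

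With untreated wild type as the control, 3641 probe sets passed for hsp-otd and 4917 for hsp-Otx2. Of the calls against heat-shocked wild type, 1827 (50.6%) and 3113 (68%) passed here too, 161 and 171 of them in the opposite direction. This contrast adds the effect of heat shock by construction. Of 115 values 80 kept direction and call, 18 lost the call, 1 gained it (oc in hsp-Otx2) and 16 reversed. For hsp-otd they were GILT3 (-0.32), Muc91C (-2.29), Ocho (-0.75), E(spl)mgamma-HLH (-0.26), Tom (-0.12), E(spl)m5-HLH (-1.04), Cpr65Ea (-2.35), TwdlW (-4.0), Ccp84Ac (-3.13), TwdlV (-1.89) and Cdk2 (-0.07). For hsp-Otx2 they were CCT8 (0.24), Ccp84Ac (-1.53), TwdlW (-3.62), TwdlF (-1.01) and Muc91C (-2.0). The named probe set of CG33253 was at the floor in all 3 groups of these contrasts.

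List shifts numbered 11 for heat shock, 6 for hsp-otd, 8 for hsp-Otx2 and 8 between the lines. Camera with an estimated correlation gave 7 for heat shock and 0 for hsp-Otx2, and the brightness covariate gave 7 for heat shock. With oc left out the shifts numbered 11, 6, 8 and 7. With fry, which asks whether a list's genes move one way and not whether they move more than others, there were 17, 18, 22 and 21. The cause was not tested. Signal limits the rest: 1737 probe sets were too dim to test, and folds of genes at the floor are lower bounds.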

Other observations

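The genes and lists named in this part were chosen after their values were seen, and the tests on other splits of the arrays were not.

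Maternal transcripts were found in hsp-Otx2 embryos: exu was at least 12.2-fold and osk at least 6.53-fold above heat-shocked wild type, where both were at the floor, with log2 fold changes of 3.60 (SE 0.27, adjusted p = 5.08e-08) and 2.71 (SE 0.25, adjusted p = 4.14e-07), n = 4 against 3. Of 15 germ line and maternal genes 5 were higher and 1 lower, and the list did not pass (camera adjusted p = 0.0825). In hsp-otd embryos osk was at the floor. The cytochrome P450 gene Cyp6a8 was higher in hsp-otd, by 2.14 over heat-shocked wild type (SE 0.12, adjusted p = 3.47e-09) and by 3.01 over hsp-Otx2 (SE 0.11, adjusted p = 1.4e-11). Against untreated wild type, midgut and digestive enzymes were 10 higher and 5 lower in hsp-otd and 17 higher and 5 lower in hsp-Otx2, with medians of 0.41 and 1.31. Mitochondrial respiration genes were 33 lower and 1 higher in hsp-otd and 44 lower and 2 higher in hsp-Otx2 in the same contrast.

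The real grouping of the arrays gave more changed probe sets than any other split in each comparison. This does not exclude chance, since the splits are few and replicates may not be separate collections. Splits that mix differing groups also have a larger residual spread, which lowers their counts. For heat shock 1 of 56 splits gave as many as the real 2770, and the highest other gave 584. For hsp-otd it was 1 of 35, with 3610 and a highest other of 371. For hsp-Otx2 it was 1 of 35, with 4577 against 1801, and between the lines 1 of 35, with 3630 against 2. For the shared changes 1 of 100 drawn splits gave as many as 1975, and the highest other gave 1437.

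Principal components 1, 2 and 3 of the normalized log2 values held 28.6%, 16% and 13.3% of the variance.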
